A study of Cucumis sativus with 12 samples.

How the data were processed

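Total RNA from cucumber ovaries and pericarps was extracted with Trizol, made into libraries with the NEBNext Ultra RNA kit and sequenced on an Illumina HiSeq instrument, per the labels. The labels give 3 biological replicates for each of 4 groups, wild type and ns mutant in ovary and pericarp, with samples frozen on the same day. Reads were aligned with TopHat2 2.0.12 per the submitters' processing notes. The genome build, the counting tool, the strandedness and the annotation release are not given in the sources used here.

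The authors deposited a read count per gene and library, whole numbers without normalization per the file headers. The authors also deposited FPKM values, by a formula not given in the sources used here. Of 18901 genes with more than 100 reads, 16851 had FPKM within 1% of the value recomputed from counts, listed length and the library's summed counts, 2050 had a higher value (up to 2.79 times) and 0 a lower one. The deposited table also holds the authors' p-value and adjusted p-value for each comparison, by a tool not given in the sources used here. From these, only the authors' adjusted p was used, to count the authors' calls. The authors' group means of normalized read counts and their columns of log2 fold change, which held entries that are not numbers, were not used here. Other per-library columns left unused came to 0. The table lists 24134 genes, of which 1852 had no reads and 886 are loci that the authors assembled.

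Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 18777 in all. Counts were scaled by TMM and fitted with the edgeR 4.0.16 quasi-likelihood model in R 4.3.3, with 4 group means and no covariate. The contrasts were ns mutant minus wild type in ovary, the same in pericarp, the difference between these (pericarp minus ovary), and pericarp minus ovary in each line. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. It is derived from the test, so for genes with few reads in a group it can be smaller than the counting error. Log2 CPM with a prior count of 2 served for principal components. Where a group had no reads, the fold was computed against a floor of 3 counts over the group, and with 1 to 3 reads the ratio of library-scaled counts is given with its exact (Clopper-Pearson) 95% interval. Total counts of 17090526 to 23069521 reads set this floor, and the intervals cover counting error only.

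The 24 gene lists, the rule for genes to be named, the contrasts and the settings that open the next paragraph were fixed before the data were examined. The plan named limma on log2(FPKM + 1), and edgeR replaced it because the table holds counts, so limma 3.58.1 became an added alternative. The trichome and spine list also holds, by identifier, the 3 genes chosen in advance. Lists are otherwise text matches on the descriptions of the deposited table, and some members match by wording only, as methylene does for ethylene. They covered auxin transport, auxin response, trichome and spine regulators, cuticle and wax, cell wall loosening and pectin, cell wall synthesis, cell cycle, histones, photosynthesis, ethylene, gibberellin, cytokinin, brassinosteroid, abscisic acid and jasmonate, flavonoid and phenylpropanoid, terpenoid and cucurbitacin, defence, heat shock, aquaporins, lipid transfer proteins, ribosomal proteins, ovule and seed markers, phloem and vascular markers, and floral organ identity markers. Each was tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted by Benjamini-Hochberg over 120 tests. Ontology terms of the deposited table with 10 to 300 tested genes were scanned the same way within each contrast. The genes named by rule were 3 chosen in advance, the 8 with the largest rise and fall in each ns contrast, the 5 largest in each direction of the difference between tissues, the 8 largest rises and falls shared by both tissue contrasts, and up to 4 members of each list. Besides the threshold, the rule for the largest changes required a mean of at least 5 FPKM in the higher group, a described protein and no overlap between the libraries compared, a condition that 10% of random splits of 3 against 3 meet. Its coding was corrected after a first selection had been seen, and the members printed from the lists were picked from the rule's output after their values were seen.

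The other settings fixed beforehand were a pseudocount of 0.1, no filter and a mean of at least 5 FPKM, quantile normalization, equal medians, no variance trend, the compared groups alone, the replicate number as a block, adjusted p under 0.01, a log2 fold change of at least 1, an estimated correlation, leaving out each library, and DESeq2 1.42.0. The alternatives limma on log2(FPKM + 1), RLE factors, library totals alone and leaving out both ovary libraries numbered 2 were chosen after seeing the data. The counts of list and term calls under each setting were added after seeing the data. On simulated data built on the ovary contrast, edgeR recovered 80 of 100 genes changed 2-fold and 47 of 100 changed 1.5-fold, and called 9 of 18517 unchanged genes. These changed genes were drawn above a bound on mean count, genes varied independently and no library was made to lie apart. The real ovary contrast called 35.82% of genes and had libraries that lay apart, so these rates may not hold there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.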

Results

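RNA sequencing measured transcript levels in fruit tissue of cucumber, Cucumis sativus, from a line labelled wild type and a line labelled ns mutant. Ovaries were sampled 6 days before flowering and pericarps, the fruit wall, on the day of flowering, so tissue and age changed together. Each of the 4 groups had 3 biological replicates by the labels, 12 libraries in all. The labels describe the material as inbred lines with numerous or few fruit spines and do not state which genotype carried which, so a difference between genotypes is a difference between lines and not of 1 gene alone. Total counts ran from 17090526 to 23069521 reads per library, and 18777 of 24134 listed genes passed the filter on low values. Counting intervals and floors given below cover counting error only.

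The first principal component held 46.8% of the variance and separated pericarp from ovary, and the second held 34.1% and separated the genotypes. The genotypes also lay apart on the first within each tissue, and the tissues on the second within each genotype. These percentages are therefore not the shares of tissue and genotype. Wild type ovary library 2 lay apart from the others of its group on the first component, at 15.02 against 39.56 and 46.12, and ns mutant ovary library 2 on the third, which held 6.59%, at 31.0 against 14.7 and 21.28. Chi-square per degree of freedom between replicates was 26.73 and 32.55 in the 2 wild type ovary pairs with replicate 2, and 42.17 and 38.63 in the corresponding ns mutant ovary pairs. It lay between 5.008 and 9.73 in the other 8 pairs of replicates. Replicate numbers did not pair the libraries across groups, with a median correlation of deviations of -0.0188 for equal numbers and 0.00728 for different numbers, described over 18 and 36 pairs.

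**Figure D1:**
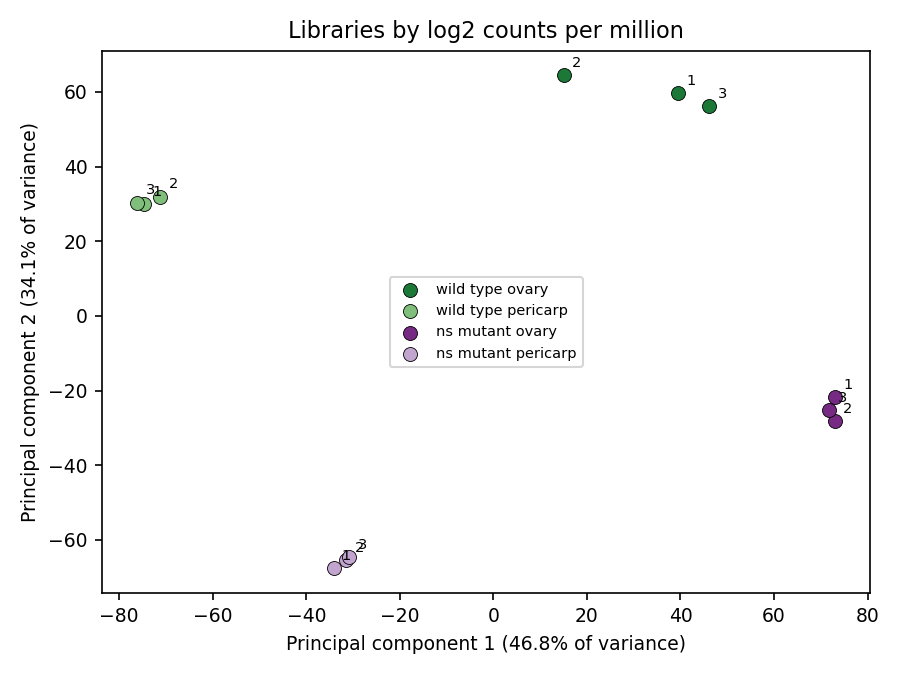
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with the replicate number beside each point and colours for the 4 groups. The first component holds 46.8% and the second 34.1% of the variance.

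In the ovary, the comparison asks which transcripts differ between the lines before flowering. Csa2M264590, annotated as auxin transporter-like protein 3 and chosen beforehand as the gene proposed for the ns locus, was lower in the ns mutant, with a log2 fold change of -1.93 ± 0.30 (SE, n = 3 per group; edgeR, Benjamini-Hochberg adjusted p 0.000562). It lies on chromosome 2 from 12795994 to 12800532 in the deposited table, whose genome build is not given in the sources used here. The mean of Csa2M264590 was 14.4 ± 3.90 FPKM in wild type ovaries and 3.55 ± 0.477 FPKM in ns mutant ovaries (SD, n = 3). The homeobox-leucine zipper genes Csa3M748220 and Csa6M514870, chosen with it, fell by 0.90 and 0.96 on the log2 scale, with SE of 0.13 and 0.15. Of the 18777 genes tested, 6725 differed at an adjusted p under 0.05, 3468 higher and 3257 lower in the ns mutant. The split between directions moved with other settings: library totals in place of TMM gave 2585 higher and 4469 lower, and limma on log2(FPKM + 1), another tool without TMM, gave 2478 higher and 4414 lower. A fit of the 6 ovary libraries alone called 4198 genes, and the authors' deposited table holds 2960 with an adjusted p under 0.05.

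Several genes of the ovary comparison were close to absent in 1 line. Csa5M577350, Csa5M478610, Csa5M478620 and Csa5M049520 were without reads in 1 line in both tissues by the rule given under other observations. For them a lost or diverged genome segment or reads assigned to a paralog stay open, besides a change in transcript level. The C2H2 zinc finger gene Csa5M577350 had 913 reads in the 3 wild type ovaries and 1 read in the ns mutant, a ratio of 899 (95% exact counting interval 161 to 35600). The pheophorbide a oxygenase gene Csa1M600170 fell by 9.51 ± 0.26 on the log2 scale, from 76.4 to 0.0902 FPKM. Oleosin gene Csa5M523090 fell by 6.97 ± 0.25. UDP-glycosyltransferase gene Csa1M687630 fell by 7.67 ± 0.26. In the group with the fewest reads, Csa1M600170 had 4 and Csa1M687630 had 10, so the SE of both may understate their error. Monooxygenase gene Csa1M242600 was 383-fold lower (106 to 3170), and the adjacent beta-amyrin synthase-like genes Csa5M478610 and Csa5M478620 were 159-fold (28.1 to 6300) and 131-fold lower (23.1 to 5210). In the other direction, the acyltransferase gene Csa3M280980 was 515-fold higher in the ns mutant (176 to 2500). The neurochondrin-like gene Csa5M049520, without a read in the wild type ovaries, was at least 43.7-fold higher against a floor of 3 counts over the group. The ribosomal protein S4 gene Csa5M212600 rose by 7.58 ± 0.34, and the ethylene-responsive factor gene Csa6M017030 by 7.53 ± 0.49, to 162 FPKM. The MADS-box gene Csa6M095280 rose by 3.26 ± 0.13, from 34.6 to 313 FPKM.

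Among the gene lists fixed beforehand, 8 of 24 passed the camera test in the ovary. The adjusted p covers all 120 tests of a list in a contrast at a preset correlation. The value beside it, marked estimated here and below, is the adjusted p with the correlation estimated from the data. Photosynthesis genes were lower for 44 of 71 members, higher for 5 and not called for 22 (median -0.448; Benjamini-Hochberg adjusted p 3.6e-08, and 0.605 with an estimated correlation). They included the chlorophyll a-b binding genes Csa7M033300 (-1.17 ± 0.14) and Csa6M522690 (-1.01 ± 0.14). Cuticle and wax genes were lower for 20 of 40 and higher for 4 (median -0.457; adjusted p 0.00149, estimated 0.536). Among them were the cytochrome P450 86A2-like gene Csa6M004550 (-1.17 ± 0.12), the ketoacyl-CoA synthase gene Csa4M649640 (-0.90 ± 0.09) and the acyltransferase gene Csa7M051300 (-1.57 ± 0.17). Lipid transfer protein genes were lower for 17 of 43 and higher for 7 (median -0.242; adjusted p 0.00105, estimated 0.536), with Csa3M026660 at -1.55 ± 0.11. Cell cycle genes were lower for 50 of 126 and higher for 16 (median -0.18; adjusted p 0.015, estimated 0.768), with the kinesin-like gene Csa5M166470 at -1.45 ± 0.13. That list lost its call without the ns mutant ovary library 2 (-0.121, adjusted p 0.139) and without both ovary libraries numbered 2 (-0.0984, adjusted p 0.267), and over 18 alternatives its adjusted p ran from 0.000658 to 0.267. Terpenoid and cucurbitacin genes were lower for 14 of 36 and higher for 6 (median -0.411; adjusted p 0.00836, estimated 0.536), and flavonoid and phenylpropanoid genes for 26 and 15 of 103 (median -0.0446; adjusted p 0.0313, estimated 0.747). Over 18 alternatives the adjusted p of the terpenoid list ran from 0.0028 to 0.792, where at a mean of 5 FPKM, with fewer members, its median changed sign to 0.0251. Its call also ended in limma on log2(FPKM + 1), with or without a variance trend (adjusted p 0.0523 in both), and without both ovary libraries numbered 2 (adjusted p 0.0993). That of the lipid transfer list ran from 3e-04 to 0.0652. Its call ended in limma on log2(FPKM + 1) with or without a trend and with a pseudocount of 0.1, and held in limma with quantile normalization (-0.259, adjusted p 0.0136).

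Heat shock genes were higher for 56 of 127 members and lower for 9 (median 0.362; adjusted p 3.17e-05, and 0.536 with an estimated correlation), with the class IV gene Csa7M072770 at 4.80 ± 0.41 and the class I gene Csa3M595190 at 6.20 ± 0.56. Phloem and vascular markers were higher for 21 of 50 and lower for 3 (median 0.315; adjusted p 0.000789, estimated 0.536). The phloem protein 2 genes Csa1M542510 and Csa1M542490 moved apart, the first rising by 6.54 ± 0.39 and the second 82.2-fold lower (22.4 to 685). Adjusted over the list alone, 61 heat shock genes were higher and 15 lower, 48 photosynthesis genes lower and 5 higher, and 22 cuticle genes lower and 4 higher. The flavonoid call ended in 9 of 18 alternatives, with adjusted p from 0.000119 to 0.541 and medians from -0.456 to 0.0118. They included library totals (-0.126, adjusted p 0.101) and the fit without wild type ovary library 3 (-0.00606, adjusted p 0.0794). The median changed sign without ns mutant ovary library 1 (0.0118, adjusted p 0.18) or 3 (0.00658, adjusted p 0.117), which ended the call too. Within it, flavanone 3-hydroxylase Csa3M002800 (-1.49 ± 0.08), flavonol synthase Csa6M040540 (-1.88 ± 0.12) and the reductase gene Novel00296 (-4.27 ± 0.12) were lower.

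The other 16 lists did not pass in the ovary in edgeR with TMM, though 6 of them did in some of 18 alternatives. Ethylene genes passed in 12 (adjusted p 0.00607 to 0.394), among them library totals (0.174, adjusted p 0.0177), and abscisic acid and jasmonate genes in 3, all in limma (0.0188 to 0.65). Ribosomal protein genes passed in limma with quantile normalization, 79 lower and 8 higher (-0.159, adjusted p 1.74e-05; others up to 0.768). Histone genes passed without ns mutant ovary library 2 (0.163, adjusted p 0.0244) and without both ovary libraries numbered 2 (0.19, adjusted p 0.0096; others up to 0.872). Trichome and spine regulators passed at a mean of 5 FPKM (-0.34, adjusted p 0.00331; others up to 0.529). Cell wall loosening and pectin genes passed without wild type ovary library 2 (-0.033, adjusted p 0.0479; others up to 0.479). In edgeR with TMM, their members higher and lower were 2 and 6 of 18 for auxin transport, 24 and 25 of 125 for auxin response, and 4 and 8 of 20 for trichome and spine regulators. They were 19 and 37 of 145 for cell wall loosening and pectin, 16 and 24 of 95 for cell wall synthesis, and 7 and 3 of 32 for histones. For hormones they were 45 and 20 of 160 for ethylene, 8 and 4 of 38 for gibberellin, 9 and 6 of 47 for cytokinin, 5 and 5 of 17 for brassinosteroid, and 35 and 16 of 86 for abscisic acid and jasmonate. The counts were 42 and 32 of 203 for defence, 7 and 10 of 29 for aquaporins, 15 and 19 of 198 for ribosomal proteins, 4 and 4 of 26 for ovule and seed markers, and 5 and 4 of 31 for floral organ identity markers. Single members moved strongly within them. Lipoxygenase Csa4M288070 fell by 6.05 ± 0.21 and allene oxide cyclase Csa5M644020 rose by 1.93 ± 0.13. Auxin transporter-like Csa7M010800 fell by 0.94 ± 0.12, and polygalacturonase Csa6M526410 fell by 2.43 ± 0.21. Aquaporin genes went both ways, with Csa6M445140 at 1.71 ± 0.19 and Csa3M743400 at -1.30 ± 0.15. In the scan of 1769 ontology terms, 5 passed at the preset correlation, among them chlorophyllide a oxygenase activity, lower for 6 of 10 genes (adjusted p 0.000233), and DNA integration, higher for 13 of 33 (adjusted p 0.0463). None of the 1769 passed with an estimated correlation by camera, where 51 had an unadjusted p under 0.05.

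**Figure D2:**
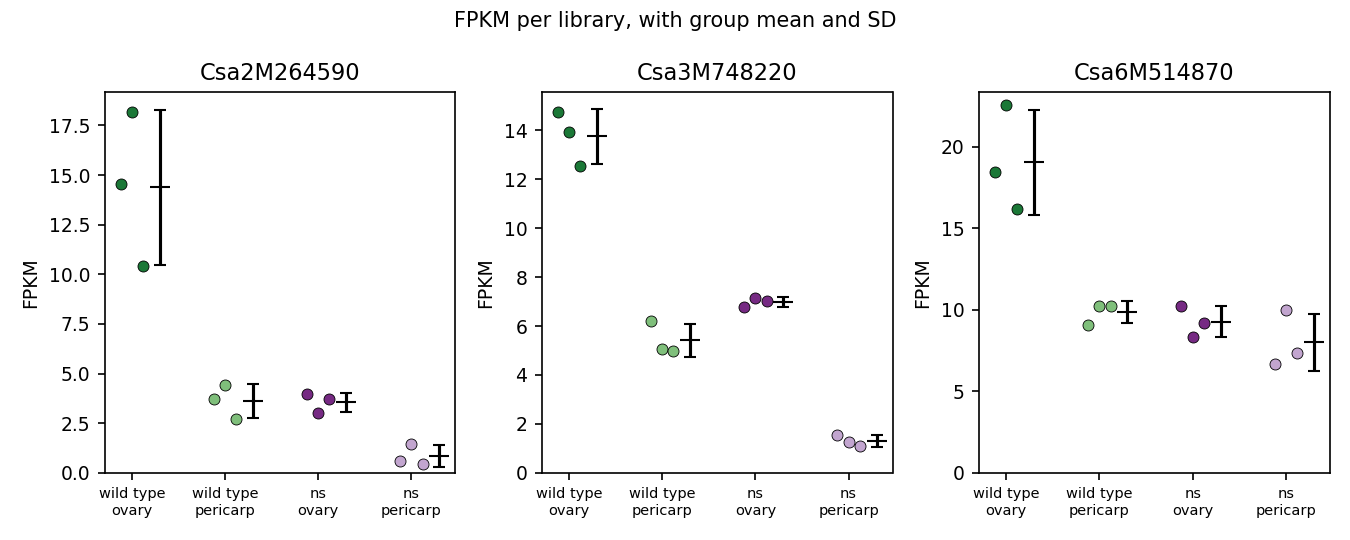
FPKM of the 3 genes chosen beforehand in each of the 12 libraries (points), with group mean and SD (bars, n = 3). Csa2M264590 averages 14.4 FPKM in wild type ovaries and 0.836 FPKM in ns mutant pericarps.

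In the pericarp, the same contrast asks which transcripts differ between the lines on the day of flowering. Csa2M264590 was again lower in the ns mutant, at -2.10 ± 0.37 (SE, n = 3 per group; edgeR, Benjamini-Hochberg adjusted p 0.000905), with 3.6 ± 0.864 FPKM in wild type and 0.836 ± 0.552 FPKM in the ns mutant (SD, n = 3). Csa3M748220 fell by 2.04 ± 0.16, and Csa6M514870 was not called (-0.28 ± 0.15; edgeR, Benjamini-Hochberg adjusted p 0.171, and 0.0221 without the ns mutant pericarp library 2). In all, 7424 genes differed, 3969 higher and 3455 lower, against 7843 in the authors' deposited table. The larger direction turned under other settings, with 3609 higher and 3737 lower for library totals in place of TMM. Limma gave 3545 and 3750 on log2(FPKM + 1), 3391 and 4160 with quantile normalization, and 3445 and 3828 with equal medians. A fit of the pericarp libraries alone called 9145 genes, more than the joint fit, where the ovary libraries alone called fewer (4198 against 6725). The joint fit shared its spread per gene across all groups, so its totals do not compare the tissues at their own spread.

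The zinc finger gene Csa5M577350 was 1960-fold lower (351 to 77300) in the pericarp, with 2054 reads against 1. The universal stress protein-like gene Novel00038, the lipid transfer protein-like gene Csa7M232580 and the farnesyl pyrophosphate synthase gene Csa5M031950 had no reads in the ns mutant pericarps and were at least 76.5-fold, at least 43.8-fold and at least 33.3-fold lower. Oleosin gene Csa5M523090 fell by 7.29 ± 0.26, Csa1M600170 fell by 6.47 ± 0.25 and phloem protein 2 gene Csa1M542490 fell by 6.57 ± 0.43. The latex protein-like gene Csa3M331340 was 82.9-fold lower (28 to 404). Higher in the ns mutant were the protein kinase gene Csa3M875440, at least 114-fold, the MLP-like gene Novel00542, at least 113-fold, and the gibberellin 20-oxidase gene Csa3M081390, at least 63-fold. The acyltransferase gene Csa3M280980 was 1270-fold higher (228 to 50400) and the short-chain dehydrogenase gene Csa1M168880 rose by 9.78 ± 0.70. The ribosomal protein S4 gene Csa5M212600 was 622-fold higher (172 to 5140), and phloem protein 2 gene Csa1M542510 rose by 6.67 ± 0.33. The senescence-associated gene Csa3M164460, at least 72.1-fold higher, and the GTP-binding protein gene Csa5M440080, at least 61.6-fold higher, were without reads in the wild type pericarps. These genes, Csa5M577350, Csa7M232580, Csa5M031950, Csa3M875440 and the universal stress protein-like gene also meet the rule for genes without reads under other observations. A lost or diverged genome segment or reads assigned to a paralog stay open for them too.

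Ribosomal protein genes were lower for 161 of 198 members and higher for 7 (median -0.363; camera, Benjamini-Hochberg adjusted p 1.03e-13, and 0.605 with an estimated correlation), among them Csa4M618420 (-1.34 ± 0.12) and Csa3M643750 (-0.76 ± 0.10). Limma with quantile normalization gave 122 lower and 8 higher (median -0.217, adjusted p 4.02e-09), the highest adjusted p of 17 alternatives, the lowest being 1.56e-21. Photosynthesis genes were lower for 52 of 71 and higher for 3 (median -0.506; adjusted p 9.99e-10, estimated 0.588), with the photosystem I subunit gene Csa6M483300 at -0.93 ± 0.12 and the thylakoid gene Csa7M428280 at -1.66 ± 0.16. Histone genes were lower for 22 of 32 and higher for 2 (median -0.428; adjusted p 1.04e-05, estimated 0.567), with H2A gene Csa6M303770 at -1.04 ± 0.11 and H4 gene Csa1M084320 at -0.65 ± 0.08. Lower by the same test were lipid transfer protein genes, with 19 of 43 lower and 4 higher (median -0.386; adjusted p 0.000247, estimated 0.536). Cuticle and wax genes were lower for 18 of 40 and higher for 5 (median -0.442; adjusted p 0.00338, estimated 0.536). Trichome and spine regulators were lower for 8 of 20 and higher for 2 (median -0.249; adjusted p 0.0064, estimated 0.536), and terpenoid and cucurbitacin genes for 14 and 4 of 36 (median -0.235; adjusted p 0.0122, estimated 0.536). The trichome list includes Csa5M577350, Csa2M264590 and Csa3M748220, given above, and its mean was -0.673. Its call is therefore not separate from the falls of these genes. Ethylene genes were higher for 50 of 160 and lower for 21 (median 0.168; adjusted p 0.0424, estimated 0.635). That call ended under quantile normalization (0.0881, adjusted p 0.0806), in limma on log2(FPKM + 1) with or without a trend (0.123, adjusted p 0.0524) and without the wild type pericarp library 3 (0.201, adjusted p 0.0685), with a range of 0.00987 to 0.0806 over 17 alternatives. A filter at a mean of 5 FPKM ended the cuticle call (-0.376, adjusted p 0.0761, from 0.000554 in the others) and the terpenoid call (0.149 with a changed sign, adjusted p 0.826, from 0.00662 in the others). Adjusted over the list alone, 170 ribosomal protein genes were lower and 8 higher, and 23 histone genes lower and 2 higher.

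Among named genes of these and other lists, the ketoacyl-CoA synthase gene Csa5M177700 fell by 3.53 ± 0.35 and the pectinesterase gene Csa7M343870 by 3.35 ± 0.33. The xyloglucan endotransglucosylase gene Csa3M845490 rose by 2.06 ± 0.16 and the AUX/IAA gene Csa7M440550 by 2.06 ± 0.17. The AUX/IAA gene Csa3M444560 fell by 1.06 ± 0.07. The WRKY gene Csa3M119700 rose by 3.76 ± 0.41, from 9.01 to 120 FPKM, the GRAS gene Csa3M405510 by 2.55 ± 0.33, and the cyclin-dependent kinase inhibitor gene Csa7M339140 by 1.14 ± 0.11. Phenylalanine ammonia-lyase gene Csa6M147460 fell by 2.41 ± 0.19, sesquiterpene synthase gene Csa3M040860 by 2.46 ± 0.28 and lipoxygenase gene Csa4M286950 by 2.18 ± 0.14. In the term scan, 3 terms passed, and RNA-directed RNA polymerase activity was higher for 20 of 48 genes (adjusted p 0.00249). None of the 1769 terms passed with an estimated correlation by camera, where 40 had an unadjusted p under 0.05.

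**Figure D3:**
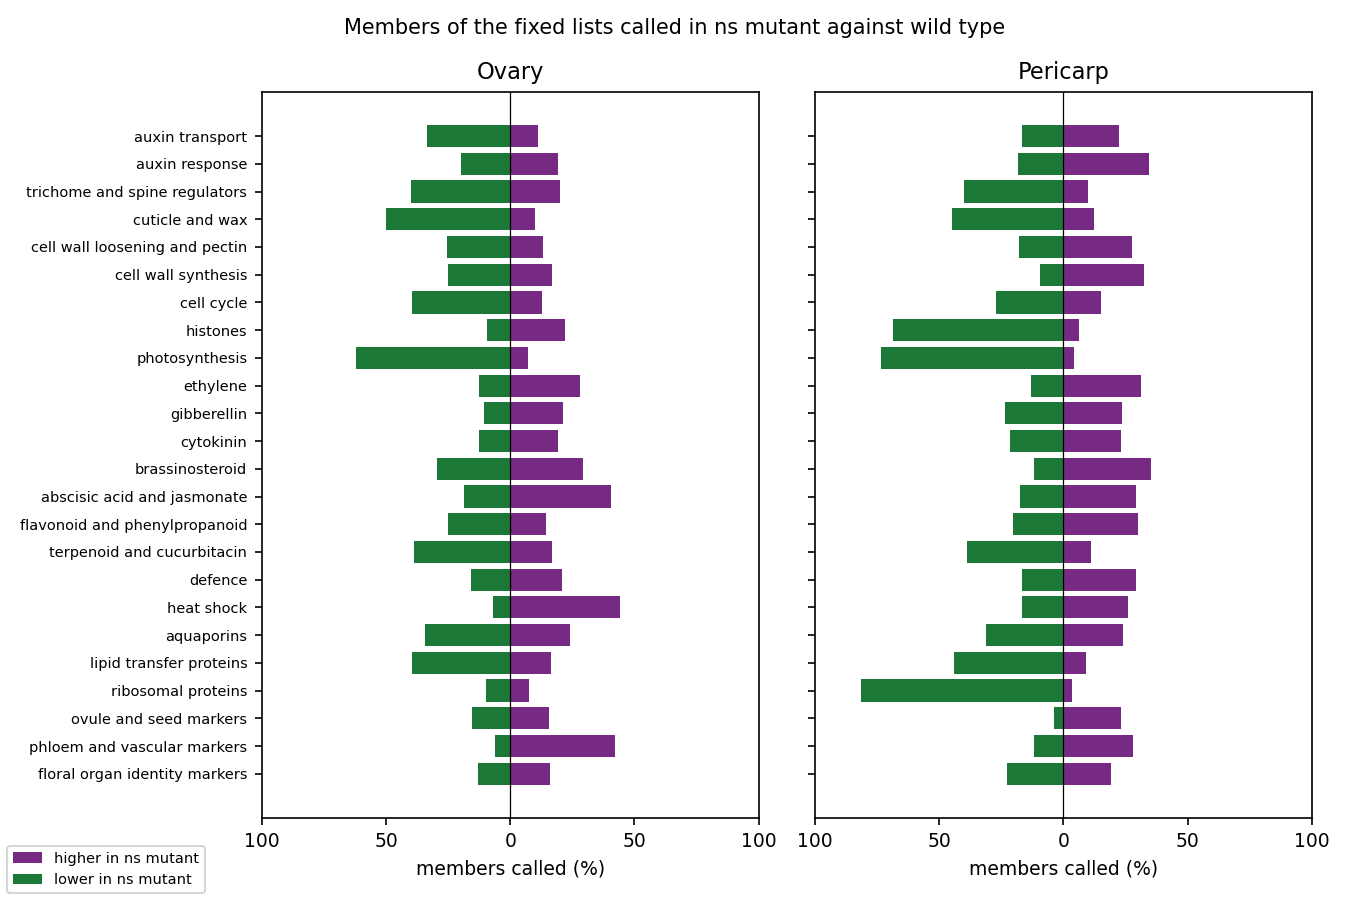
Share of the members of each of the 24 fixed lists called higher (to the right of 0) or lower (to the left) in the ns mutant, in percent of the members, in ovary and pericarp. By edgeR with TMM, as drawn, 161 of 198 ribosomal protein genes were lower in the pericarp and 19 in the ovary. Limma with quantile normalization gave 122 and 79, and edgeR with library totals 172 and 52.

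Across both tissues, 3365 genes were called in the same direction, 1752 higher and 1613 lower in the ns mutant, where independence would give 733.1 and 599.3. In opposite directions 234 were called, against 1327 expected. The contrasts share no library, but 1 fit with a spread per gene shared by all groups gave both, so their calls are not independent. Their fold changes had a Pearson r of 0.725 and a Spearman correlation of 0.534 across genes, which are not independent replicates.

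The difference of the ns effect between tissues, pericarp minus ovary, asks whether the line difference depends on tissue and age. It was called for 2624 genes, 1406 positive and 1218 negative. Within edgeR with TMM the larger direction turned without wild type ovary 1 (821 and 941), ns mutant ovary 1 (1297 and 1481) or ns mutant ovary 3 (929 and 1012). It held without each of the other libraries. With library totals in place of TMM the split was 1823 and 920. In limma on log2(FPKM + 1) it was 1768 and 977, and equal medians within limma turned that to 1061 and 1580. Csa3M748220 fell further in the pericarp (-1.15 ± 0.21; n = 3 per group, edgeR, Benjamini-Hochberg adjusted p 0.00695), while Csa2M264590 did not differ by this test (-0.17 ± 0.47, edgeR, Benjamini-Hochberg adjusted p 0.843). Csa6M514870 missed the threshold (0.68 ± 0.21, edgeR, Benjamini-Hochberg adjusted p 0.0529). The ribosome-inactivating protein gene Csa5M428440 had the most negative value among the genes named, -8.31 ± 0.55, rising from 2.56 to 38.7 FPKM in the ovary and falling from 6.01 to 0.296 FPKM in the pericarp. The UDP-glycosyltransferase gene Csa1M687630 had 4.99 ± 0.34, the phospholipase A1 gene Csa1M537320 4.90 ± 0.73 and the aminocyclopropane carboxylate synthase gene Csa4M049610 4.87 ± 0.93. Csa6M017030 (-6.25 ± 1.71), Csa3M081390 (5.14 ± 1.29) and Csa1M630850 (-6.44 ± 1.61) lost their calls without single libraries, and the last 2 had no reads in a pericarp group, so that their fitted values depend on the prior count. For Csa6M017030 these were each wild type pericarp library (edgeR, Benjamini-Hochberg adjusted p 0.0542, 0.253 and 0.0553), wild type ovary 1 (0.051) and ns mutant pericarp 2 and 3 (0.0564 and 0.0575). For Csa3M081390 they were wild type pericarp 1 and 3 (edgeR, Benjamini-Hochberg adjusted p 0.0611 and 0.0547), wild type ovary 1 and 2 (0.0937 and 0.051) and ns mutant pericarp 2 (0.0554). For Csa1M630850 they were wild type pericarp 1 and 2 (edgeR, Benjamini-Hochberg adjusted p 0.0687 and 0.122) and ns mutant pericarp 3 (0.0507). The replicate number as a block ended the calls of Csa3M081390 and Csa1M630850 as well (edgeR, Benjamini-Hochberg adjusted p 0.0547 and 0.0522). Without single pericarp libraries the count fell to 1596 (wild type 1), 1707 (wild type 3), 1542 (ns mutant 2) and 1684 (ns mutant 3). It rose without wild type ovary 2 (2934), ns mutant ovary 1 (2778) or 2 (3143), and without both ovary libraries numbered 2 (4012). Without the other single ovary libraries it fell, to 1762 (wild type 1), 1890 (wild type 3) and 1941 (ns mutant 3).

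By list, histone genes were more negative in the pericarp for 23 of 32 members (median -0.498; camera, Benjamini-Hochberg adjusted p 1.03e-13, and 0.536 with an estimated correlation) and ribosomal protein genes for 62 of 198 (median -0.331; adjusted p 8.2e-17, estimated 0.567). Limma with quantile normalization gave histones a median of -0.259, 6 negative (adjusted p 0.000122), and ribosomal proteins -0.0758, 6 negative and 3 positive (adjusted p 0.0383). Limma without it gave medians of -0.44 and -0.269. These were the highest adjusted p of 23 alternatives, the lowest being 2.9e-18 and 4.05e-24. Heat shock genes were negative for 21 of 127 and positive for 5 (median -0.202; adjusted p 0.000295, estimated 0.536), and phloem and vascular markers for 4 and 2 of 50 (median -0.31; adjusted p 0.00633, estimated 0.567). Cell wall synthesis genes were positive for 25 of 95 and negative for 3 (median 0.238; adjusted p 0.000634, estimated 0.536). Flavonoid and phenylpropanoid genes were positive for 21 of 103 and negative for 5 (median 0.284; adjusted p 0.00105, estimated 0.597), and cell wall loosening and pectin genes for 23 and 4 of 145 (median 0.0919; adjusted p 0.015, estimated 0.536). The phloem call ended without the wild type ovary library 2 (-0.266, adjusted p 0.0588) and without both ovary libraries numbered 2 (-0.152, adjusted p 0.131; range over 23 alternatives 0.00125 to 0.131). The cell wall loosening call ended in limma with a pseudocount of 0.1 (0.128, adjusted p 0.0649) and without both ovary libraries numbered 2 (0.117, adjusted p 0.0502; from 0.00174 in the others). Protein folding, lower for 19 of 110 genes, was the 1 term called (adjusted p 0.021), and none of 1769 passed with an estimated correlation by camera, where 60 had an unadjusted p under 0.05.

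Pericarp against ovary compares tissue and age together within each line. The rapid alkalinization factor gene Csa6M484570 rose by 8.15 ± 0.26 in wild type and 8.50 ± 0.27 in the ns mutant (log2, SE, n = 3 per group), to 91.1 and 89.5 FPKM. The MYB gene Csa3M837580 rose by 7.66 ± 0.39 and 7.57 ± 0.41, and the CRABS CLAW-like gene Csa5M606780 had -7.42 ± 0.21 and -3.78 ± 0.16. Of the 18777 genes, 8327 differed in wild type, 4192 higher and 4135 lower in the pericarp, and 9921 in the ns mutant, 4984 higher and 4937 lower. The ns mutant split moved to 5924 and 3806 in limma on log2(FPKM + 1), and turned to 4555 and 5191 with equal medians in limma and to 4843 and 5085 with RLE factors, which turned the wild type split to 4104 and 4232. DESeq2 turned both, to 4020 and 4243 in wild type and 4719 and 4953 in the ns mutant. The authors' deposited table holds 6827 and 7048 genes with an adjusted p under 0.05. In both lines 2942 genes were higher and 2676 lower in the pericarp, against 1113 and 1087 under independence, and 203 went opposite ways. Here too the spread per gene was shared, so the calls are not independent.

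Further genes higher in the pericarp of both lines were the legumin-like gene Csa3M218170 (6.90 ± 0.44 in wild type, 7.54 ± 0.46 in the ns mutant) and the galactosyltransferase gene Csa5M647250 (7.12 ± 0.32 and 6.55 ± 0.33). The same held for the oligopeptide transporter gene Csa3M047870 (7.64 ± 0.72 and 5.02 ± 0.56) and the zinc finger homeodomain gene Csa5M636500 (6.36 ± 0.49 and 6.21 ± 0.60). The 11S globulin gene Csa3M218160 was 732-fold higher in wild type (131 to 29000) and lipoxygenase gene Csa2M023920 126-fold (43 to 615). The pectinesterase gene Csa7M447990 rose by 2.82 ± 0.11 and 3.11 ± 0.11, aquaporin gene Csa5M162580 by 2.51 ± 0.20 and 2.50 ± 0.20, and the lipid transfer gene Csa3M027210 by 6.39 ± 0.37 and 4.97 ± 0.34. Lower in the pericarp were the WUSCHEL-related gene Csa6M518270 (-5.66 ± 0.17 and -5.51 ± 0.16), the GH3 genes Csa3M198490 (-5.39 ± 0.44 and -5.28 ± 0.43) and Csa6M492310 (-6.65 ± 0.68 and -3.34 ± 0.50), and the hydrolase gene Csa3M016920 (-5.14 ± 0.30 and -7.02 ± 0.38). The Hsp90 gene Csa3M183950 (-4.14 ± 0.88 and -7.02 ± 0.83), the DREB1B gene Csa5M174570 (-7.34 ± 0.76 and -3.06 ± 0.51) and the bridging factor gene Csa2M004720 (-5.11 ± 0.70 and -5.01 ± 0.66) were lower too. Of the 3 genes chosen beforehand, Csa2M264590 (-2.02 ± 0.30 and -2.19 ± 0.37) and Csa3M748220 (-1.37 ± 0.14 and -2.51 ± 0.16) were lower in the pericarp of both lines. Csa6M514870 was lower in wild type (-0.97 ± 0.15) and not called in the ns mutant (-0.29 ± 0.15; edgeR, Benjamini-Hochberg adjusted p 0.125). There it passed without both ovary libraries numbered 2 (-0.37, edgeR, Benjamini-Hochberg adjusted p 0.0388) and without pericarp library 2 (-0.49, edgeR, Benjamini-Hochberg adjusted p 0.0132). Efflux carrier genes moved apart, with Csa1M042820 at -1.82 ± 0.11 and Csa1M025070 at 2.89 ± 0.15 in wild type.

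Of the lists, 7 passed in wild type and 13 in the ns mutant. Photosynthesis genes were higher in the pericarp for 51 of 71 members in wild type (median 0.536; camera, Benjamini-Hochberg adjusted p 1.49e-10, and 0.568 with an estimated correlation) and 45 in the ns mutant (median 0.564; adjusted p 6.42e-07, estimated 0.635). Phloem and vascular markers were higher for 30 and 27 of 50 (medians 1.02 and 0.731; adjusted p 4.92e-10 and 0.000114, estimated 0.536 in both). Aquaporins were higher for 14 and 17 of 29 (medians 0.457 and 0.538; adjusted p 0.0112 and 0.0257, estimated 0.536 in both). Trichome and spine regulators, which include the genes chosen beforehand, were lower for 11 and 12 of 20 (medians -0.531 and -0.746; adjusted p 0.00502 and 0.000105, estimated 0.536 in both). Cuticle and wax genes were lower for 20 and 16 of 40 (medians -0.451 and -0.316; adjusted p 0.00196 and 0.0063, estimated 0.536 in both). The trichome call in wild type ended without the wild type ovary library 2 (-0.497, adjusted p 0.114) and without both ovary libraries numbered 2 (-0.496, adjusted p 0.25; range over 18 alternatives 0.000876 to 0.25). Abscisic acid and jasmonate genes were lower for 39 of 86 in each line (medians -0.337 and -0.361; adjusted p 0.00689 and 0.00122, estimated 0.536 in both). Ethylene genes were lower for 61 and 71 of 160 (medians -0.244 and -0.412; adjusted p 0.015 and 0.0409, estimated 0.605 and 0.635). Another 6 lists passed in the ns mutant and not in wild type. Ribosomal protein genes were lower for 150 of 198 (median -0.368; adjusted p 4.92e-10, estimated 0.635), against 13 in wild type (median -0.0287; adjusted p 0.682). Histone genes were lower for 28 of 32 (median -0.574; adjusted p 7.61e-08, estimated 0.536), against 4 in wild type (median -0.00179; adjusted p 0.816). Limma with quantile normalization brought the ns mutant medians to -0.132 for ribosomal proteins (75 lower, adjusted p 0.00131) and -0.296 for histones (19 lower, adjusted p 0.000375), from -0.282 and -0.486 in limma without it. These were the highest adjusted p of 18 alternatives, the lowest being 4.16e-15 and 5.06e-10. Heat shock genes were lower for 72 of 127 (median -0.446; adjusted p 8.21e-05, estimated 0.536) and for 48 in wild type (median -0.279; adjusted p 0.138). In wild type they passed with the replicate number as a block (-0.274, adjusted p 0.0433), without ovary library 2 (-0.342, adjusted p 0.00207) and without both ovary libraries numbered 2 (adjusted p 0.000125; others up to 0.242). Cell wall synthesis genes were higher for 45 of 95 in the ns mutant (median 0.362; adjusted p 0.0015, estimated 0.536), against 34 in wild type (median 0.161; adjusted p 0.416). Cell wall loosening and pectin genes were higher for 62 of 145 (median 0.308; adjusted p 0.0117, estimated 0.536), against 48 in wild type (median 0.0377; adjusted p 0.549). The difference between tissues, given above, was called for these 5 lists. Auxin transport genes were higher for 10 of 18 in the ns mutant (median 0.741; adjusted p 0.0105, estimated 0.536) and 9 in wild type (median 0.481; adjusted p 0.0968, and 0.0416 to 0.223 over 18 alternatives). Their difference was not called (median 0.126; adjusted p 0.249), so the lines are not shown to differ in this list. In the ns mutant the ethylene call ended without pericarp library 1 (-0.462, adjusted p 0.0576) or ovary library 2 (-0.291, adjusted p 0.16), without both ovary libraries numbered 2 (-0.291, adjusted p 0.0912) and at a mean of 5 FPKM (-0.21, adjusted p 0.196), with a range of 0.00307 to 0.196. The aquaporin call ended without ovary library 1 (0.479, adjusted p 0.0501), with a range of 0.0131 to 0.0687. It also ended in limma on log2(FPKM + 1), with or without a trend, and with a pseudocount of 0.1. The same 3 limma fits ended the auxin transport call (adjusted p up to 0.0961, from 0.00503) and the cell wall loosening call (up to 0.107, from 0.0041). Limma with quantile normalization ended the first (0.381, adjusted p 0.0602) and not the second (0.233, adjusted p 0.0383), and limma with equal medians ended neither. Terms passed for 5 of 1769 in wild type, among them serine-type carboxypeptidase activity, higher for 16 of 28 genes (adjusted p 0.00227), and for 14 in the ns mutant, among them glycolytic process, higher for 21 of 35 (adjusted p 0.0276). None passed with an estimated correlation by camera, where 39 and 76 had an unadjusted p under 0.05. Of the 77 tests of a list not called, 21 passed in at least 1 alternative at the preset correlation. Over all contrasts, none of the 43 calls at the preset correlation held with an estimated one, and in 17 of the 120 tests, none of them called, median, mean and test differed in sign.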

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

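The 3 tests on heat shock genes were chosen after the result was seen, and 2 of them were later moved from the members called in the ovary to the whole list, and the number of draws for the splits of the difference between tissues was raised from a smaller number after a first result. The difference of the ns effect between pericarp and ovary, tested as an interaction in edgeR, passed an adjusted p (Benjamini-Hochberg) of 0.05 for 2624 genes and for 44 of the 112 genes named by rule, 24 positive and 20 negative. In 4 of these 44 a group held 3 reads or fewer, so that the fitted value depends on the prior count: Csa1M630850, Csa3M081390, Csa3M081890 and Csa4M415930.

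Negative values on the log2 scale, meaning a lower ns effect in the pericarp than in the ovary, were -8.31 for Csa5M428440, -7.44 for Csa6M055940, -6.44 for Csa1M630850, -6.25 for Csa6M017030, -5.53 for Csa6M007450, -4.86 for Csa7M072770, -3.33 for Csa5M177700, -1.85 for Csa7M343870, -1.68 for Csa5M644020 and -1.62 for Csa7M447000. Smaller ones were -1.15 for Csa3M748220, -1.11 for Csa6M505280, -1.08 for Csa4M645290, -0.99 for Csa3M760500, -0.99 for Csa3M119760, -0.97 for Csa4M286950, -0.85 for Csa6M303770, -0.82 for Csa6M127300, -0.75 for Csa3M444560 and -0.71 for Csa1M084320. Positive values were 5.25 for Csa4M415930, 5.14 for Csa3M081390, 4.99 for Csa1M687630, 4.90 for Csa1M537320, 4.87 for Csa4M049610, 4.28 for Csa5M174570, 3.86 for Csa3M081890, 3.64 for Csa5M606780, 3.52 for Csa3M119700, 3.31 for Csa6M492310, 3.05 for Csa1M600170 and 2.25 for Csa3M405510. Smaller ones were 2.20 for Csa1M616240, 2.12 for Csa3M845490, 2.07 for Csa6M526410, 1.72 for CsaUNM012430, 1.08 for Novel00296, 0.97 for Csa7M440550, 0.84 for Csa3M127760, 0.84 for Csa5M576590, 0.55 for Csa6M004550, 0.48 for Csa3M002800, 0.46 for Csa4M649640 and 0.36 for Csa1M575010. By camera at the preset correlation 7 lists differed, with medians of 0.0919 for cell wall loosening and pectin, 0.238 for cell wall synthesis, 0.284 for flavonoid and phenylpropanoid, -0.498 for histones, -0.331 for ribosomal proteins, -0.31 for phloem and vascular markers and -0.202 for heat shock.

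Other splits of the libraries were fitted the same way. For the difference between tissues, 4 of 100 drawn splits (of 200 possible, the real one included) gave as many genes as the real 2624. This does not exclude a chance split, because 79 draws mixed the lines in both tissues, which turns the line effects into spread within groups, and so could not test the difference. Of the 11 draws that kept the real lines in the pericarp, 4 gave as many: the real split, an exchange of the lines, and splits with 3071 and 2652 genes. The latter splits mixed the lines in the ovary only, so they count the line effect of the pericarp. They are no null for the difference between tissues. The highest other split gave 9271 genes and exchanged the lines in 1 tissue, which turns the difference into a sum of both line effects, a structure of the samples. The highest split without such an exchange gave 3071. Each 3 against 3 contrast has 10 splits, too few for a share under 0.05: 1 split, the real one, gave 6725 genes in the ovary against at most 4 in the others, 7424 in the pericarp against 0, 8327 for the tissues in wild type against 0 and 9921 in the ns mutant against 0. The other splits mix the compared groups, which turns their difference into spread within groups. Low counts there were thus fixed by the design and are no null for the real count.

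Heat shock genes were higher in the ns mutant ovary, with a median of 0.362 over 127 members. Without both ovary libraries numbered 2 the median was 0.289 (SE 0.0933 over genes), above 0.5 of its value with all libraries (0.181) by little more than that SE. This argues against those libraries as the whole cause, by a narrow margin. The SE treats members as independent and does not measure the spread between libraries. Of the 56 members called higher, 53 were called again, but both fits share the remaining ovary libraries, so this is no separate support. A line difference of similar size in both tissues cannot be told apart: over all 127 members the pericarp median was 0.238 (SE 0.0639), above 0.5 of the ovary median (0.181) by less than its SE. In the pericarp the list had 33 members higher and 21 lower and did not pass camera (adjusted p 0.507), but passed with the pericarp libraries fitted alone (52 higher and 23 lower, median 0.217; adjusted p 0.0436, the lowest of 17 alternatives, the highest being 0.661). The list's difference between tissues passed camera at the preset correlation (median -0.202; adjusted p 0.000295) and not with an estimated one (0.536). Of the 56 members called higher in the ovary, 20 were called higher in the pericarp and 0 lower. Different handling of the ovary samples cannot be told apart from the line, since the design has no handling factor apart from the group. The list's median level ranged over 0.379 within wild type ovaries, against 0.315 between the ovary groups, and over 0.326 within ns mutant ovaries. Without the ovary libraries numbered 2 these ranges were 0.0347 and 0.227, against 0.265 between the groups, so library 2 made most of the wild type range and less of the other. A difference between the lines in ovaries of this age stays open and untested.

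Ribosomal protein genes were lower in the ns mutant pericarp, with a median of -0.363 over 198 members. Other genes matched on length and mean FPKM had a median of -0.141 (SD 0.0299 over draws), against 0.00795 over all tested genes. Length or level may thus account for part of the fall. The matched median was smaller in size than 0.5 of the list's median by little more than that SD, which argues against length or level as the whole cause. All draws came from the same 10 neighbours per gene, so the SD may understate the error. In limma with quantile normalization the list lay at -0.177 relative to all genes (SE of its median 0.0192), against -0.369 in limma without it and -0.371 in edgeR with TMM. This passed the bound set beforehand, 0.5 of the value, by less than the SE, so scaling between libraries may account for part of the fall. Quantile normalization would also shrink a real fall shared by many genes of similar level, so it cannot tell these apart. The list's median was -0.359 with RLE factors, -0.39 with library totals and -0.393 in limma with equal medians. Those scalings shift all genes alike and cannot decide either. A difference between the lines in the pericarp stays open and untested.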

How the results depend on the processing

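The counts of list and term calls under each setting and the alternatives limma on log2(FPKM + 1), RLE factors, library totals and leaving out both ovary libraries numbered 2 were chosen after seeing the data. At an adjusted p under 0.01 the counts fell to 3822 (ovary), 4727 (pericarp), 710 (difference between tissues) and 1819 (shared between tissues), and with a log2 fold change of at least 1 to 1683, 1841, 809 and 875, and to 2500 and 2751 for pericarp against ovary in wild type and ns mutant, since both are stricter thresholds on the same fit. The ovary libraries alone gave 4198 genes and the pericarp libraries alone 9145. Without both ovary libraries numbered 2 the difference between tissues rose to 4012. Leaving out each library gave 5223 to 6377 genes in the ovary, 5903 to 6279 in the pericarp, 1542 to 3143 for the difference between tissues, 6581 to 8282 and 8528 to 9896 for the tissue contrasts, 2800 to 3549 shared genes, 42 to 46 list calls and 22 to 46 terms, with 46 terms without the ns mutant ovary library 2. The 28 terms called became 73 without a filter, 48 at a mean of 5 FPKM, 15 with the compared groups alone, 11 in limma with either pseudocount and without trend, and 9 with equal medians. With an estimated correlation, 0 lists of 43 and 0 terms of 28 stayed called by camera. At a mean of 5 FPKM the median of terpenoid genes in the ovary changed sign to 0.0251 (camera, adjusted p 0.792), with 6 members called higher and 3 lower, against 6 and 14 before. That filter takes out members of low level, among them Csa5M478610 and Csa5M478620, so the members compared are not the same. The cause was not tested for the fits of 1 tissue alone, for the ovary libraries numbered 2, for the terms or for this list. Fits of 1 tissue alone take the spread per gene from that tissue only, where the main fit shares it across groups. Against edgeR with TMM no other scaling moved a median over all genes by more than 0.1, but for pericarp against ovary in the ns mutant it ran from -0.0287 in limma with equal medians to 0.0791 with library totals. The threshold alternatives do not apply to camera, and the difference between tissues has no fit of fewer groups. Low counts limit genes with 3 reads or fewer in a group.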

Other observations

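Both tests on genes without reads were planned before their results were seen. With at most 3 reads in both groups of 1 line and a mean of at least 1 FPKM in the other, 17 tested genes were without reads in the ns mutant and 53 in wild type, of which 6 and 36 are loci assembled by the authors. Chromosome 5 held 22 of its 2486 tested genes (0.885%) and chromosome 3 held 18 of 3940 (0.457%). A genome segment lost or diverged in 1 line may contribute: 4 pairs of such genes were neighbours, where the middle 95% of 10000 random draws reached at most 1. Adjacent copies or pieces of 1 transcript would also give pairs, as for Csa5M478610 and Csa5M478620. The same may hold for Csa5M031950 and CsaUNM020190, each close to an assembled locus without reads in the same line. The draws took any tested gene, of which 712 of 18777 are assembled loci, so they do not match the genes without reads in this respect. Reads assigned to a nearby paralog cannot be told apart from a lost or diverged segment, since only 5 genes had a partner of the same annotation within 200 kb, which is too few. Of these, 1 had a partner called in the opposite direction in the ovary (20%, exact 95% interval 0.505 to 71.6%). It was the zinc finger gene Csa5M577350, a member of the trichome and spine list. Its partner Csa5M576700 had a log2 fold change of 2.307 in the ovary and -0.1158 in the pericarp, the latter not opposite. The share to compare was 17.9%, from the ovary calls of all tested genes if directions split evenly. In the pericarp the partner of Csa5M190450, another of the 5, was called in the opposite direction (log2 fold change -0.3404).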
